A study of Mus musculus with 4 samples.

How the data were processed

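The data were 4 Clariom S mouse gene expression arrays, 1 for each population of macrophages sorted from mouse hearts after transverse aortic constriction (TAC). Total RNA was reverse transcribed, amplified with a whole-transcript kit made for small inputs, biotin-labelled and hybridised, per the labels' protocols. The array intensities were background-corrected, normalized and summarised per probe set by robust multichip average (RMA) by the authors, per the labels' protocols, which also name GeneSpring, and the submitters' processing notes name Affymetrix Expression Console. The RMA settings and the annotation build of the probes are not given in the sources used here. The deposited values are on the log2 scale, 1 column per library, and ran from 2.97 to 19.93, which is the log2 of 1000000 and acted as a ceiling of the scale. The log2 scale was read from the values. Medians over all probe sets were 5.19 in Ccrl2, 5.32 in CD74, 5.32 in CD163 and 5.21 in Trem2, and the spread of values differed between columns. The 95th percentiles were 10.09, 8.45, 9.06 and 10.21 in the same order. Whatever normalization was applied, the deposited columns thus did not share a distribution, and counts on these values carry that difference.

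The top of the scale was coarse. Among the 96 probe sets with a mean between 17 and 19.9, 35.4% had identical values in the Ccrl2 and Trem2 libraries, 29.2% in Ccrl2 and CD163 and 31.2% in CD163 and Trem2, against 0.67%, 0.45% and 0.45% of the 14561 probe sets with a mean between 5 and 8. Differences between 2 values near the top are therefore poorly resolved, and large ones are given as log2 differences. Values within 0.015 of 19.93 were treated as saturated, which held for 24 named genes in Ccrl2, 9 in CD74, 16 in CD163 and 20 in Trem2. Some genes repeated a value under 19.93, such as Spi1 at 19.72 in Ccrl2, CD163 and Trem2. Such genes were not counted as saturated.

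Of 28846 probe sets, 6640 were controls. Of the 22206 gene probe sets, 19572 had 1 gene symbol in the platform annotation, 0 had several and 2634 had none. All 19572 were matched to mouse genes of the GRCm38.p6 assembly's gene table by gene number, and no symbol needed an update. Where a gene had several probe sets, which held for 55 genes, the one with the highest mean over the 4 libraries was used, leaving 19505 genes. The background ceiling of a library was the 95th percentile of its values for 1497 olfactory, vomeronasal and taste receptor and keratin-associated protein genes. Genes above the ceiling in at least 1 library numbered 9362, and only these entered the comparisons. A gene was counted as higher in a library when it lay above that library's ceiling and at least 1 log2 unit (2-fold) above each of the other 3 libraries. A gene was counted as lower when it lay at least 1 log2 unit below each of the other 3 and above their ceilings. Where a value lay under its ceiling or was saturated, a fold is a lower bound, computed with the dim value set at the ceiling, and is written as "at least".

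With 1 library per group no test, standard error or standard deviation could be had, and p-values across genes were not computed. Whether a gene list stood apart was described by the median over its measured members of the difference between a library and the mean of the other 3. That median was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. A list was said to stand apart under the 2.5th or over the 97.5th percentile, a range that leaves out 5% of random lists. Percentiles are printed to 3 significant digits, so that 0 and 100 stand for values that round to them. The 29 lists held 551 genes, of which 505 had a probe set and 417 were above the ceiling in at least 1 library. Counts of list members at least 2-fold apart used the deposited values, also where these lay under a ceiling.

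The libraries, the rule for calling genes, the lists and the rule for naming genes were fixed before the data were examined. Named were the sort marker genes, the 12 genes with the largest margin over and the 8 with the largest margin under the other libraries in Ccrl2, 8 and 4 such genes in each other library, the 4 largest differences each way between Ccrl2 and each other library, and up to 4 members of a list with the largest differences. Predicted and unnamed genes, small RNA genes, antigen receptor segments, histones, chemosensory receptors and sex-linked marker genes were left out of this naming. Alternatives were quantile normalization and median centring of the columns, no filter and a filter at each library's median, the mean over probe sets, 1.5-fold and 4-fold thresholds, the mean of the other 3 libraries as reference, leaving out each library, 5 bins, list means, and lists without shared members. Leaving out genes saturated in any library was added after the data were seen.

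The calling rule was tested on simulated libraries with the 19505 genes, a noise SD of 0.3 log2 units and 200 genes raised in the Ccrl2 library. It called 23.5% of the raised genes at 2-fold, 99.0% at 4-fold and 100% at 8-fold, with 3, 4 and 3 other genes called. That noise was smaller than in the data, where the differences of the 1497 background genes between pairs of libraries had an SD across genes, not across replicates, of 0.58 to 0.85. The simulated rates are therefore no estimate for these arrays, on which 5 background genes were counted as higher in Ccrl2, 51 in CD74, 29 in CD163 and 2 in Trem2. In a simulated shift of 0.5 log2 units of the interferon list, over 8454 genes, that list lay at percentile 100, and 3 of the 28 other lists lay outside the central range. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.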

Results

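The study profiled macrophages sorted from the hearts of C57BL/6N mice, 15 to 16 weeks old, after TAC, a surgical narrowing of the aorta that loads the left ventricle with pressure. Cells of 6 hearts were mixed and sorted into 4 populations, named Ccrl2, CD74, CD163 and Trem2 macrophages after their titles, and each gave 1 library on 1 array. The labels disagree on some points. Source names put the surgery 8 weeks before sampling and the growth protocol puts it 1 week before. The library titled CD74 carries CD9 in its source name, and the growth protocol lists a Lyve1 population where the titles have CD163. The libraries are named by title throughout. Since every population was 1 library, no difference below has a replicate check, and the number of arrays limits the precision of every value.

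All levels are the deposited log2 values. The background ceiling was 5.67 in Ccrl2, 6.53 in CD74, 6.28 in CD163 and 5.50 in Trem2, and 7454, 3621, 4984 and 8171 genes lay above it. The CD74 and CD163 arrays thus measured fewer genes over a higher background. The chance that a positive control probe set exceeded a negative one was 0.748 in Ccrl2, 0.63 in CD74, 0.672 in CD163 and 0.745 in Trem2. The hybridisation control bioB had 8.29, 6.15, 8.49 and 8.12 in the same order. The control bioC had 9.24, 7.57, 10.46 and 9.20 and bioD 10.77, 10.31, 12.62 and 10.75, both lowest in CD74 like bioB. The hybridisation control cre had 11.17, 12.34, 13.16 and 11.07, so not every control was lowest in CD74. Over the 9362 genes measured in at least 1 library, the median difference from the mean of the other 3 libraries was 0.39 in Ccrl2, -0.59 in CD74, -0.28 in CD163 and 0.55 in Trem2. After quantile normalization these medians were 0.15, -0.29, -0.11 and 0.18. Random lists share this general shift, so each list median is given with the median of its random lists.

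The first comparison asked whether the transcripts of the sort markers followed the labels. Cd163, a scavenger receptor for haemoglobin complexes, had its highest value in the CD163 library (14.51), with 13.11 in Trem2, 13.01 in Ccrl2 and 4.96, below the ceiling, in CD74. Lyve1, a hyaluronan receptor of resident macrophages, reached the top of the scale in CD163, against 14.32 in Trem2, 13.88 in Ccrl2 and 5.56, below the ceiling, in CD74. Ccrl2, an atypical receptor that binds chemerin, had 16.58 in the Ccrl2 library and 16.59 in the Trem2 library, with 14.00 in CD163 and 9.58 in CD74. Trem2, a lipid-sensing receptor, had 7.20 in the Trem2 library, 7.17 in Ccrl2, 6.71 in CD163 and 5.94, below the ceiling, in CD74. The values of Ccrl2 and Trem2 transcripts therefore did not separate the Ccrl2 and Trem2 libraries, and their order turned with scaling, with Trem2 at 6.95 in Ccrl2, 6.91 in CD163 and 6.87 in Trem2 after quantile normalization. Cd9, a tetraspanin, had 8.69 in the library titled CD74, 9.35 in CD163, 10.79 in Ccrl2 and 11.65 in Trem2, and after quantile normalization 9.76 in CD74 and 9.70 in CD163, so that CD74 was then no longer the lowest. The Cd74 gene was not analysed here.

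**Figure D1:**
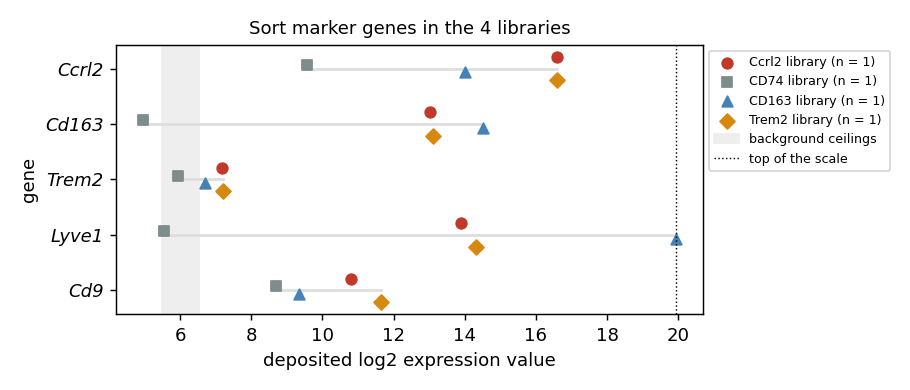
Deposited log2 values of 5 sort marker genes (horizontal axis) in the Ccrl2, CD74, CD163 and Trem2 libraries, 1 point per library and no error bars since n = 1. The grey band spans the background ceilings from 5.50 to 6.53 and the dotted line is the top of the scale, which Lyve1 reached in CD163.

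The Ccrl2 population is the one in the series title, and the next comparison asked which genes set it apart from the other 3. Genes of inflammation, the interferon response and matrix turnover were among those with the largest excess. Tnf, a central inflammatory cytokine, had 18.78 in Ccrl2 against 15.38 in CD163, 15.04 in Trem2 and 5.55, below the ceiling, in CD74, a 10.6-fold excess over CD163. Il1a, an alarmin cytokine, had 12.03 against 9.09 and 9.03 in CD163 and Trem2. In all, 341 genes were at least 2-fold above each other library and 16 at least 2-fold below each. Of the 341, 5 were background genes (chemosensory receptors and keratin-associated proteins).

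Among genes of matrix and proteolysis, Fn1, which encodes fibronectin, had 11.32 in Ccrl2 and 8.19 in Trem2, an 8.75-fold difference. Mmp12, the macrophage elastase, was 7.01-fold and Plau, the urokinase plasminogen activator, 6.45-fold above Trem2. Serpinb2, an inhibitor of that protease, was at least 5.78-fold and Prg4, which encodes lubricin, at least 10.1-fold above the nearest library. Sdc4, a heparan sulphate proteoglycan, had 16.26 against 13.32 in CD163. Among antiviral genes, Ifih1, a sensor of double-stranded RNA, was 6.19-fold above Trem2, Ifit2 at least 5.66-fold above the nearest library, and Tank, an adaptor of NF-kB and interferon signalling, 5.54-fold above CD163. Rasgef1b, an exchange factor for Ras-like proteins, was 5.78-fold above CD163.

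The genes lower in Ccrl2 had smaller margins and mostly low levels. Gzma, a granzyme of cytotoxic lymphocytes, had 4.54 in Ccrl2, below the ceiling, against 6.42 in CD163, 9.71 in Trem2 and 13.01 in CD74. Slc12a2, a sodium, potassium and chloride cotransporter, had 5.72 against 7.17 or more elsewhere. Ggnbp2 was 2.91-fold, Cracd 2.62-fold and Lrrc47 2.48-fold below the nearest library, and the fold of Lrrc47 slipped under 2 after quantile normalization (-0.99 on the log2 scale). Adh6-ps1, Spata46 and Prr30 were below the ceiling in Ccrl2, with 7.09, 6.43 and 5.58 in Trem2. The Trem2 value of Prr30 lay under the Ccrl2 ceiling of 5.67, so no decrease against Trem2 is shown for that gene. Quantile normalization gave 186 higher and 27 lower genes, 178 and 11 of them shared with the counts above. Leaving out the Trem2 library gave 2218 higher and 90 lower genes, leaving out CD74 398 and 70, and leaving out CD163 479 and 130.

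**Figure D2:**
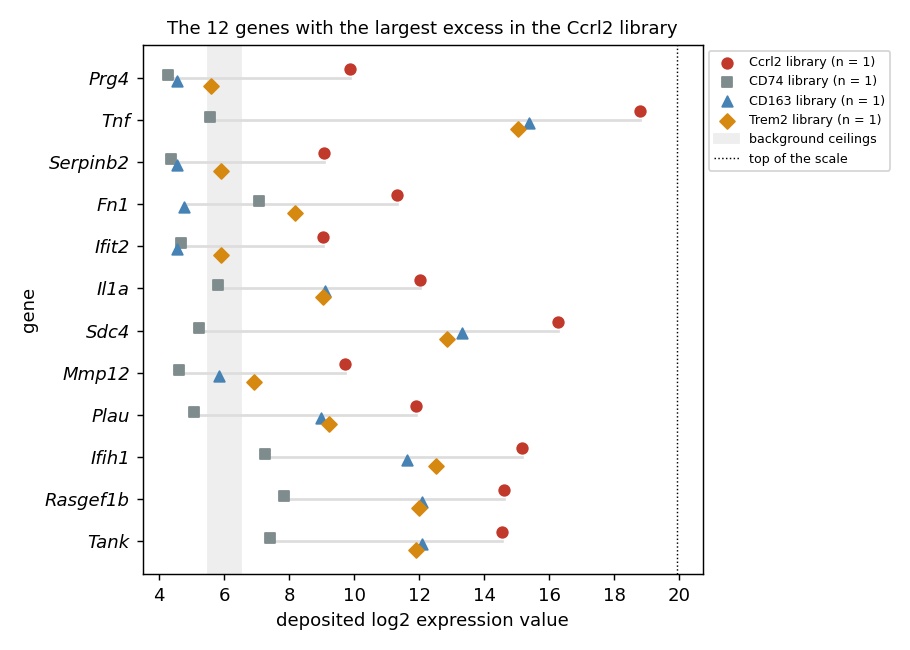
Deposited log2 values (horizontal axis) of the 12 genes with the largest excess in the Ccrl2 library, 1 point per library and no error bars since n = 1. For each gene the Ccrl2 point lies to the right of the other 3, from 9.03 for Ifit2 to 18.78 for Tnf, and the CD74 point lies below 8.

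The gene lists set the Ccrl2 library against the mean of the other 3. Of 26 measured inflammatory NF-kB targets, 21 were at least 2-fold above the mean of the other 3 libraries in Ccrl2 and 0 at least 2-fold below, with a list median of 1.99 against 1.01 for random lists (percentile 100). Besides Tnf and Il1a, this list held Nlrp3, the inflammasome sensor, with 14.75 in Ccrl2 and 12.91 in Trem2, and Bcl2a1b, a survival gene, with 13.06 and 12.04. Against the Trem2 library alone this list did not stand apart, with a median of 0.27 against 0 for random lists (percentile 96.0), 8 members at least 2-fold higher and 5 at least 2-fold lower, among the latter Clec4e (8.62 against 12.28) and Ptgs2 (10.12 against 12.90). Of 25 interferon response genes, 18 were at least 2-fold above, with a median of 1.65 against 0.45 (percentile 100). Cxcl10, a chemokine induced by interferon, had 19.46 in Ccrl2, 18.03 in Trem2 and 16.06 in CD163, and Rsad2, an antiviral enzyme, had 9.59, 7.81 and 6.39. Both lists stayed at percentile 100 when the CD74 library was left out.

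Immediate early and dissociation stress genes, which respond within minutes to tissue digestion and sorting, were also high in Ccrl2. Of 21, 20 were at least 2-fold above the mean of the others, with a median of 2.62 against 1.20 (percentile 100, and 98.0 without CD74). Against the CD163 library alone the list did not stand apart, with a median of 1.07 against 1.17 (percentile 39.8). There 11 of 21 were at least 2-fold higher and 0 lower. The heat shock genes Hspa1a and Hsph1 had 17.94 and 14.70 in Ccrl2 against 17.42 and 12.47 in Trem2, and Fosb had 19.03 against 17.52. Matrix remodelling and growth factor genes were at least 2-fold above in 11 of 16 cases (median 1.38 against 0.53, percentile 99.9), with the collagenase Mmp13 at 10.98 in Ccrl2 and 9.08 in Trem2. Class II antigen presentation genes were above in 10 of 14 (1.65 against 0.96, percentile 98.4), led by the activation marker Cd83 at 19.35 and H2-Eb1 at 14.38. That list lay at 97.1 after quantile normalization, at 94.7 without members shared with other lists and at 47.1 without the CD163 library. Pan-macrophage genes were above in 13 of 15 (percentile 99.9) and efferocytosis genes, for the uptake of dead cells, in 14 of 20 (99.8), but without CD74 they lay at 78.7 and 62.2. Csf1r, the receptor for the macrophage growth factor, had 19.59, and Axl, a receptor for dying cells, 13.29.

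Markers of other cell types also differed. Fibroblast genes were at least 2-fold above the mean of the others in 9 of 14 cases in Ccrl2 (median 1.36 against 0.47, percentile 100), with Dcn, which encodes decorin, at 12.65 in Ccrl2 and 12.67 in Trem2. Endothelial genes were above in 10 of 14 (percentile 98.9, 96.4 with the mean over members and 85.9 without CD74), with Cdh5 at 10.86. Monocyte genes lay low as a list (median -0.38 against 0.52, percentile 0.03), though 11 of 19 lay within 2-fold of the mean of the others. At least 2-fold lower were 5, and 3 were at least 2-fold higher, among the latter Fn1. Ly6c2 had 6.90 against 10.98 in Trem2 and 12.55 in CD74, and the integrin gene Itgal 5.65 against 10.05 in Trem2. Without the Trem2 library that percentile was 10.8. Neutrophil genes had a median of -1.19 against 0.43 (percentile 0, and 40.4 without Trem2), and T and NK cell genes -1.45 against 0.22 (percentile 0, and 1.70 without CD74).

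**Figure D3:**
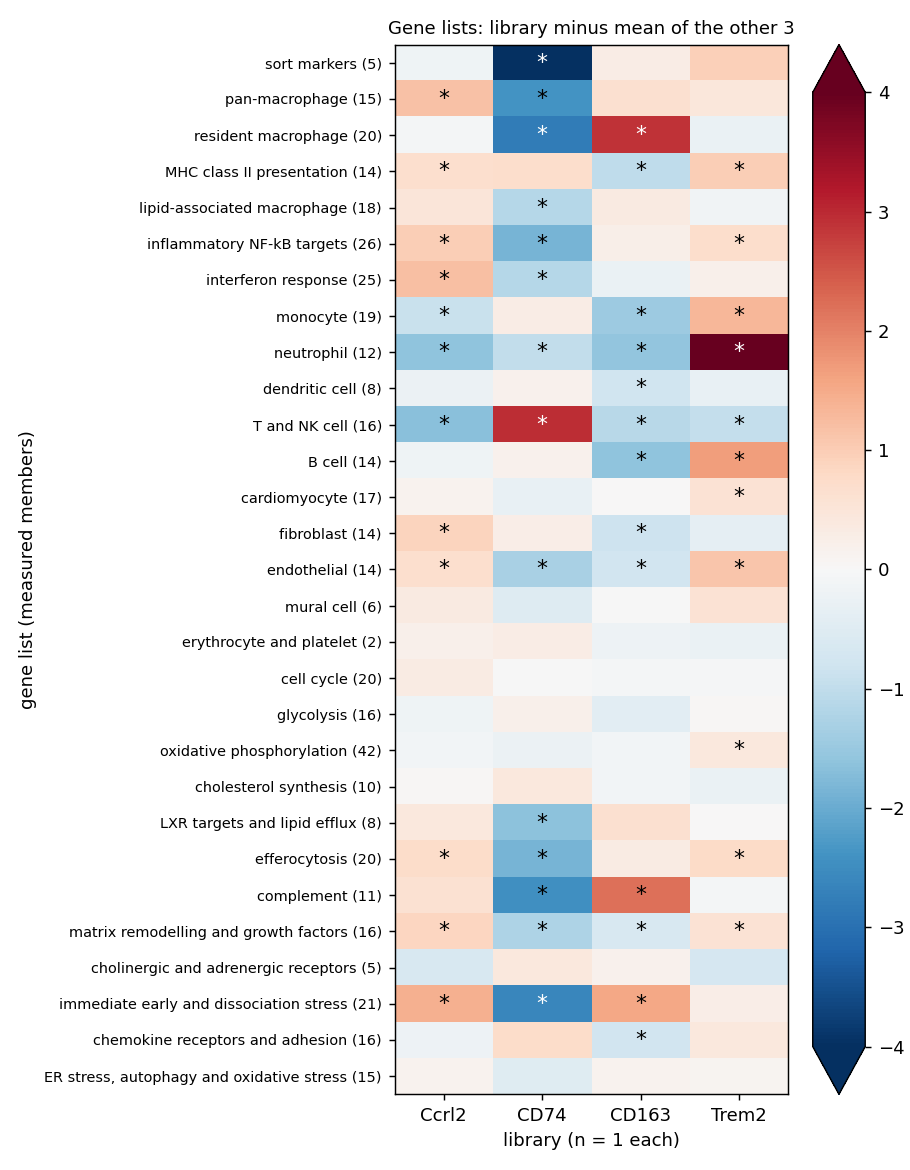
Median over the measured members of each of 29 gene lists (vertical axis, number of measured members in brackets) of the log2 difference between a library (horizontal axis, n = 1 each) and the mean of the other 3, minus the median of matched random lists. Colours stop at 4 log2 units either way, and asterisks mark the 50 of 116 values outside the central 95% of random lists, among them neutrophil genes in Trem2 and T and NK cell genes in CD74.

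Set against the Trem2 library alone, the nearest of the 3, the Ccrl2 library was higher in interferon and stress genes and lower in neutrophil and monocyte genes. The largest differences upward were Prg4 (4.28 log2 units), Tnf (3.74), Sdc4 (3.41) and Serpinb2 (3.17). Those downward were Retnlg, a resistin-like gene of neutrophils (-9.98), Lcn2, an iron-scavenging granule protein (-7.47), and the calprotectin genes S100a8 (-6.62, a bound with Ccrl2 below its ceiling) and S100a9 (-5.36). The list medians were 0.52 for interferon genes (percentile 100, 12 of 25 at least 2-fold higher and 1 lower), 0.76 for stress genes (99.9, 9 of 21 higher), 0.70 for fibroblast genes (100, 4 of 14 higher) and 0.45 for matrix genes (99.3, 7 of 16 higher and 4 lower). They were -4.17 for neutrophil, -1.67 for monocyte, -1.45 for B cell and -0.90 for chemokine receptor genes, which all lay at or under the 0.02 percentile, with 11 of 12, 13 of 19, 9 of 14 and 7 of 16 at least 2-fold lower. The random lists of these 8 lists had medians from -0.09 to 0. Of 8792 genes, 683 were at least 2-fold higher and 1007 at least 2-fold lower in Ccrl2, or 561 and 633 after quantile normalization. Beside this, 8.95% of the background genes and 39.7% of 63 ribosomal protein genes were as far apart.

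Against the CD163 library, the Ccrl2 library was higher in antigen presentation and interferon genes and lower in genes of resident macrophages. H2-Eb1 and H2-Ab1, class II chains, were 7.59 and 6.84 log2 units higher, Fn1 at least 32.9-fold and the membrane protein gene Plxdc2 84.4-fold. Lyve1 (at least 66.3-fold, with CD163 saturated), the folate receptor gene Folr2 (-5.01), the membrane protein gene Emp1 (-4.11) and the complement receptor gene Vsig4 (at least 16.4-fold, with Ccrl2 below its ceiling) were lower. Interferon genes had a list median of 2.04 against 0.55 for random lists, class II genes 2.28 against 1.08 and inflammatory genes 1.93 against 1.11, all above percentile 99.7, while resident macrophage genes had -1.08 against 1.02 (percentile 0). Markers of other cell types were higher in the same comparison, fibroblast genes at 2.19 against 0.62 (percentile 100), endothelial genes at 1.72 against 0.74 (99.7) and B cell genes at 1.48 against 0.48 (99.9). At least 2-fold higher were 3038 and lower 604 of 7891 genes, or 1889 and 1022 after quantile normalization, 3281 and 1860 without the background filter and 3226 and 1524 with a filter at the library median. Of background and ribosomal protein genes, 21.6% and 68.3% were as far apart.

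Against the CD74 library, the Ccrl2 library was higher in macrophage and inflammatory genes and lower in T and NK cell genes. Hmox1, which encodes the haem-degrading enzyme, had 19.58 against 7.34, Cxcl10 19.46 against 8.14, Tnf 18.78 against 5.55 and Sdc4 16.26 against 5.23, the last 2 below the ceiling in CD74. Lower in Ccrl2 were Gzma (at least 162-fold), Il2rb (at least 75.6-fold), Ly6c2 (50.2-fold) and Il7r (at least 18.0-fold). On the deposited values, with no ceiling applied, all 16 T and NK cell genes measured in at least 1 library were at least 2-fold lower. Their list median was -2.92 against 0.46 for random lists (percentile 0). Inflammatory genes had a median of 3.75 against 1.84 and interferon genes 2.52 against 0.82, both at percentile 100. B cell genes did not stand apart (0.14 against 0.65, percentile 8.54), with 1 of 14 at least 2-fold higher and 3 lower. Endothelial genes (2.77 against 1.11, 11 of 14 higher and 1 lower) and stress genes (5.12 against 2.29, 20 of 21 higher) lay at percentile 100. Monocyte and neutrophil genes lay at 2.15 and 2.08, but at 7.11 and 2.89 after quantile normalization. Of 7902 genes, 3858 were at least 2-fold higher and 712 lower, or 2775 and 1428 after quantile normalization, 4138 and 2548 without the background filter and 4060 and 2127 with a filter at the library median. Of background and ribosomal protein genes, 24.7% and 46.0% were as far apart, beside the 3621 genes above the ceiling in CD74.

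The CD163 library stood out by genes of resident cardiac macrophages. Lyve1 was at least 48.8-fold above Trem2, the nearest library, Folr2 had 14.94 against 10.43 in Trem2, Emp1 14.20 against 10.09 in Ccrl2, and Ednrb, an endothelin receptor, 11.17 against 8.02 in Ccrl2. Vsig4 was 8.82-fold and Cfp, which encodes the complement factor properdin, 5.82-fold above Trem2, and Prl8a8 and Rnase13 were at least 1.51-fold and 1.59-fold above ceilings that the other libraries did not pass. H2-Ab1 (10.31 against 16.01 or more) and H2-Eb1 (6.79 against 11.38 or more) were lowest in CD163, as were Fam107b (8.22 against 13.20 or more) and Cytip, a leukocyte adhesion regulator, which lay below its ceiling at 5.04. Of 20 resident macrophage genes, 18 were at least 2-fold above the mean of the others (median 2.47 against -0.42, percentile 100), among them F13a1, a coagulation factor chain, at 17.36. Complement genes were above in 9 of 11 (1.90 against -0.30, percentile 100), with C3ar1 at 15.36 in CD163, 15.92 in Ccrl2 and 5.54 in CD74. Stress genes were above in 11 of 21 (percentile 100, and 97.1 without CD74). The mean of the others includes the low CD74 values. Against Ccrl2 alone, 10 of 20 resident macrophage genes were at least 2-fold higher in CD163 and 1 lower. Of 11 complement genes, 2 were higher and 0 lower there. Without CD74 these 2 lists lay at percentiles 100 and 99.8.

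Several lists, among them markers of other leukocytes, lay low in CD163, while cardiomyocyte, mural cell, and erythrocyte and platelet genes did not stand apart (percentiles 51.5, 47.9 and 35.7). Class II genes were at least 2-fold below the mean of the others in 9 of 14 cases (median -1.48 against -0.45, percentile 0.38), monocyte genes in 12 of 19, neutrophil genes in 10 of 12, B cell genes in 11 of 14 and fibroblast genes in 8 of 14, each at or under the 0.05 percentile for the last 4. T and NK cell genes were below in 10 of 16 (percentile 0.01, but 54.1 without CD74), dendritic cell genes in 4 of 8 (2.08, but 10.1 without CD74, 3.62 without Trem2 and 2.61 without Ccrl2) and endothelial genes in 7 of 14 (0.81, but 12.2 without Trem2, 2.83 without Ccrl2, 22.3 without the background filter and 3.72 without shared members). Dendritic cell genes lay at 7.73 with the mean over members and 7.02 without the filter. Chemokine receptor genes were below in 9 of 16 (0.84, but 9.79 without Trem2 and 8.24 without shared members) and matrix genes in 8 of 16 (1.43, but 59.0 without Ccrl2 and 4.99 without Trem2). Matrix genes also lay at 2.53 after quantile normalization, 15.2 without the filter, 19.7 with the mean and 30.0 without shared members. Cd79a, a subunit of the B cell receptor, had 6.31 in CD163 and 9.66 or more in the others. Genes counted as higher numbered 264, 29 of them background genes, and as lower 441, of which 34 were ribosomal protein genes, against 479 and 368 after quantile normalization. Without CD74 the counts were 436 and 2238. The 264 came from 19505 genes and the 29 from 1497 background genes, so background genes were called higher at a greater rate than all genes. The count of 264 by itself thus shows no excess over background.

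The CD74 library had T and NK cell genes high and macrophage genes low. Cd3e, a T cell receptor subunit, had 9.50 in CD74 and lay below the ceiling elsewhere, at least a 9.32-fold difference. Il2rb, an interleukin receptor of NK and T cells, had 11.91 against 7.76 in Trem2, and the T cell genes Il7r, Lef1, Themis and Cd8a and the cytotoxic granule gene Nkg7 were at least 11.8-fold, 11.2-fold, 3.66-fold, 3.32-fold and 11.1-fold above the nearest library. Dusp10, a MAP kinase phosphatase, had 14.14 against 9.69. Of 16 T and NK cell genes, 15 were at least 2-fold above the mean of the others (median 2.53 against -0.41, percentile 100). Genes counted as higher numbered 413, 51 of them background genes, and as lower 1455, against 885 and 1160 after quantile normalization, and 3225 were lower without CD163. The 413 came from 19505 genes and the 51 from 1497 background genes, so background genes were called higher at a greater rate than all genes. The count of 413 by itself thus shows no excess over background.

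Macrophage genes were far lower in CD74, on the array with the lowest separation of positive from negative controls (0.63). Mrc1, the mannose receptor, had 9.46 in CD74 and was saturated in the other 3, Hmox1 had 7.34 against 17.96 or more, the heat shock gene Hspa1b 8.24 against 18.45 or more, and Tnf lay below the ceiling. Of 15 pan-macrophage genes, 14 were at least 2-fold below the mean of the others (median -3.96 against -1.57, percentile 0.23), with Csf1r at 9.40 and the Fc receptor gene Fcgr3 at 10.47. Resident macrophage genes were below in 17 of 20 (-4.06 against -1.27, percentile 0), inflammatory genes in 22 of 26, interferon genes in 20 of 25, stress genes in 20 of 21, efferocytosis genes in 15 of 20 and complement genes in 9 of 11, with C1qa at 7.97. Without members shared with other lists, complement genes lay at 14.6 and efferocytosis genes at 2.96, inside the central range, against 0.38 and 0 with them. Lipid-associated macrophage genes (14 of 18), matrix genes (12 of 16), endothelial genes (10 of 14), the sort markers (5 of 5) and lipid efflux genes (5 of 8) also lay under the 2.5th percentile, the sort markers at 0.35 and lipid efflux genes at 2.03. The sort markers lay at 2.57 without saturated genes, endothelial genes at the edge of the central range with the mean over members, and lipid efflux genes at 5.72 with the mean, 5.22 without shared members, 4.67 without saturated genes, 2.72 without CD163 and the edge of that range without Ccrl2. Class II genes did not stand apart (percentile 92.9), with H2-Aa at 16.03 and H2-Ab1 at 16.01, nor did monocyte genes (85.0), with Ly6c2 at 12.55. Neutrophil genes lay at 0.35, but at 99.5 without Trem2, 13.2 with the mean and 2.54 after quantile normalization.

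The Trem2 library was led by neutrophil genes. Retnlg had 16.81 against 7.15 in CD74, the nearest library, Lcn2 13.23, S100a9 12.55 and S100a8 12.29, against values below 8 in each other library, and Ngp, a granule protein, was at least 11.1-fold above its nearest library. Hcar2, a receptor for hydroxybutyrate, was 30.3-fold, Hdc, which makes histamine, 29.4-fold and Acod1, which makes itaconate, 28.8-fold above Ccrl2. Of 19 neutrophil genes with a probe set, 12 were measured, and a gene could enter through Trem2 alone, which favours a high count. Of the 12, 11 were at least 2-fold above the mean of the others (median 4.91 against 0.57, percentile 100, also without the background filter). Monocyte genes were above in 15 of 19 (2.05 against 0.71, percentile 100), with Plac8 at 12.52 and Thbs1 at 10.86. B cell genes were above in 12 of 14 (2.20 against 0.51, percentile 100), with Cd79a at 11.80 and Cd79b at 10.26. Lipid-associated macrophage genes, the list that holds Trem2, did not stand apart, with 7 of 18 at least 2-fold above (0.65 against 0.79, percentile 25.9).

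Most other lists that stood apart in Trem2 no longer did without 1 of the other libraries, while endothelial genes (11 of 14) lay at 100 with all and at 99.9 or more without each. Inflammatory genes (19 of 26 at least 2-fold above the mean of the others), efferocytosis genes (13 of 20) and matrix genes (9 of 16) lay at percentiles 100, 100 and 99.0, but at 37.2, 8.77 and 17.5 without CD74, and matrix genes at 90.9 after quantile normalization and 47.2 without the background filter. Without shared members efferocytosis genes lay at 95.6 and matrix genes at 97.4. Class II genes (11 of 14) lay at 100 and at 91.1 without CD163, cardiomyocyte genes (11 of 17) at 99.1, at 92.8 without CD163, 96.9 without CD74 and 93.9 with the mean, and oxidative phosphorylation genes (23 of 42) at 99.8, at 95.8 without CD163, 96.3 without Ccrl2 and 96.2 after quantile normalization. Among endothelial genes, Fabp4, a fatty acid carrier of capillary cells, had 17.09. T and NK cell genes lay at percentile 0, at 2.67 with the mean and at 96.9 without CD74. The few genes lower in Trem2 were led by Fbf1, 3.27-fold below CD163, with Zscan26 and Zfp987 at least 2.29-fold and 1.71-fold and Lrrc51 2.40-fold below Ccrl2. Genes counted as higher numbered 529, 2 of them background genes, and as lower 20, against 213 and 20 after quantile normalization, with 212 and 13 shared. Without Ccrl2 the counts were 2471 and 105, and the lower count was 93 without CD74 and 49 without CD163.

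Across the 9362 measured genes, which are not independent replicates, the Spearman correlation was 0.88 between Ccrl2 and Trem2, 0.728 between Ccrl2 and CD163 and 0.693 between CD163 and Trem2. The CD74 library correlated at 0.521 with Ccrl2, 0.563 with CD163 and 0.533 with Trem2. Over the same 9362 genes, the median absolute difference was 0.48 log2 units between Ccrl2 and Trem2, 0.74 between CD74 and CD163 and 0.80 between Ccrl2 and CD163. It was 0.85 between CD163 and Trem2, 1.04 between Ccrl2 and CD74 and 1.12 between CD74 and Trem2. On that measure CD163 was the library nearest to CD74. The order turned over the genes above the ceiling in at least 1 library of a pair. There the Spearman correlation with CD74 was 0.368 for CD163, 0.467 for Ccrl2 and 0.511 for Trem2. The Ccrl2 and Trem2 arrays also had similar ceilings (5.67 and 5.50) and control separation (0.748 and 0.745). The CD74 and CD163 arrays both had fewer genes above the ceiling (3621 and 4984). Nearness of the populations therefore cannot be told apart from likeness of the arrays.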

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

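Probe sets without a gene symbol entered no comparison, and some of these 2634 differed between libraries. At least 2-fold above each other library and above the background ceiling were 32 of them in Ccrl2, 63 in CD74, 61 in CD163 and 67 in Trem2. Of the 1497 background genes, the same rule called 5, 51, 29 and 2 in the same order. As a share, the unnamed probe sets in CD74 thus showed no excess over background, and those in CD163 lay near it. At least 2-fold below each other library were 3 in Ccrl2, 134 in CD74, 59 in CD163 and 4 in Trem2. Their transcripts are unnamed here, and no explanation was tested.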

How the results depend on the processing

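No paired analysis was possible because each group had 1 library. Leaving out genes saturated in any library was chosen after the data were seen and, like median centring and the mean over probe sets, kept every count of genes within 1.5 times. Quantile normalization gave 186 higher and 27 lower genes in Ccrl2, and 885, 479 and 213 higher genes in CD74, CD163 and Trem2. Without the background filter 88 genes were lower in Ccrl2, 1016 higher in CD74, 541 higher in CD163 and 119 lower in Trem2. A filter at the library median, which lies under the ceiling, gave 56, 945, 513 and 71. A 1.5-fold threshold gave 975 higher and 53 lower genes in Ccrl2, 536 and 701 in CD163, 1293 and 47 in Trem2, and 3695 genes apart between Ccrl2 and Trem2. A 4-fold threshold gave 31 and 0 in Ccrl2, 118 and 651 in CD74, 31 and 117 in CD163 and 67 and 0 in Trem2, and 2184, 1041 and 194 genes apart between Ccrl2 and CD74, CD163 and Trem2. Against the mean of the other 3 the counts were 2411 and 80 in Ccrl2, 670 and 2403 in CD74, 777 and 1032 in CD163 and 2856 and 70 in Trem2. These thresholds and filters change the counts by construction, and for quantile normalization the cause was not tested.

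Leaving out 1 of the other libraries gave 398 to 2218 higher and 70 to 130 lower genes in Ccrl2, 447 to 538 and 1546 to 3225 in CD74, 345 to 436 and 475 to 2238 in CD163, and 670 to 2471 and 49 to 105 in Trem2. A gene then has to stand apart from fewer libraries, which raises each count by construction.

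Of 116 list values, 50 (43.1%) lay outside the central range, where random lists would give 5%. The 116 values are not independent, since members of a list can vary together, lists share members and the values of a list in the 4 libraries are linked. The 5% is therefore no expected share for these lists. Over 7 alternative settings 33 of the 50 kept their side in each, 29 kept it without each other library, and 25 in both. The share outside ran from 36.8% without CD74 to 48.3% without CD163. Without the background filter matrix genes in Trem2 lay at 47.2. Percentiles that crossed the middle when a library was left out ranged from 37.2 (without CD74) to 100 for inflammatory genes, 8.77 (without CD74) to 100 for efferocytosis genes, 17.5 (without CD74) to 99.5 for matrix genes and 0 to 96.9 (without CD74) for T and NK cell genes, all in Trem2. In CD163 they ranged from 0 to 54.1 (without CD74) for T and NK cell genes and from 2.20 to 59.0 (without Ccrl2) for matrix genes. Class II genes in Ccrl2 ranged from 47.1 (without CD163) to 99.98, and neutrophil genes in CD74 from 0.01 to 99.5 (without Trem2). The cause was not tested. Among 511 values of named genes, the difference from the mean of the others changed sign in 3 under quantile normalization, Ccrl2 in CD163 (0.17), Gapdh in CD74 (0.02) and Srebf2 in Trem2 (-0.32), and in 1 under median centring, Rgs5 in CD163 (-0.03), and the cause was not tested. Depth of signal limits the CD74 library most, where 3621 genes lay above the ceiling.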

Other observations

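Glycolysis genes had a median of -0.60 log2 units in Ccrl2 minus Trem2 against -0.03 for random lists (percentile 0.35, and 4.35 with the mean over members), with 4 of 16 at least 2-fold lower, 2 higher and 10 between. Oxidative phosphorylation genes had -0.36 against -0.05 (0.53), with 7 of 42 lower and 35 between, and cholesterol synthesis genes did not stand apart (percentile 80.9). Slc2a1, the main glucose transporter, had 9.55 in Trem2 and 8.08 in Ccrl2, and Slc16a3, a lactate exporter, 9.37 and 6.90. Pfkfb3, an activator of glycolysis, and the hexokinase gene Hk2 went the other way, with 10.69 and 7.89 in Ccrl2 and 8.59 and 6.27 in Trem2. Cardiomyocyte genes, a marker of carried-over heart muscle RNA, had a median of -0.56 against -0.04 in this pair (percentile 0.74, and 8.56 with the mean), with 3 of 17 at least 2-fold lower, 1 higher and 13 between, and Myl2 at 12.50 in Ccrl2 and 13.39 in Trem2. Ccr7, a homing receptor of dendritic and T cells, had 14.97 in CD74 against 11.68 or less elsewhere.

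Of the 29 lists, 7 stood apart in none of the libraries. These were cell cycle genes (percentiles 35.4 to 93.8), glycolysis (7.61 to 70.4), cholesterol synthesis (18.5 to 86.4), stress of the endoplasmic reticulum, autophagy and oxidation (21.0 to 66.5), mural cells (8.27 to 92.7), erythrocytes and platelets (31.4 to 66.7, with 2 measured genes) and cholinergic and adrenergic receptors (9.77 to 83.8). Of the last list 20 genes had a probe set and 5 were above the ceiling in any library, with the highest value 6.97 for Chrna1 in CD74, so most genes of this list were not detectable on these arrays, and 1 of the 5, Ache, encodes an enzyme.

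Among the tests below, those of the signal range of the CD74 and Trem2 arrays and those on transcripts carried by macrophages were chosen only after the result was seen. The second marker lists and both tests on ribosomal protein genes were set after the patterns had been seen but before the values of these tests.

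In CD74, T and NK cell genes were high and macrophage genes low. A narrower signal range of that array, taken as a rescaling of its values, does not account for either. Quantile normalization left the T and NK list at percentile 100, with a median 3.90 above that of random lists against 2.94 before. The pan-macrophage list lay at 0.24, with -2.32 against -2.39. Quantile normalization keeps the order of genes within an array, so it cannot show whether signal was lost there. A second list of T and NK genes had 18 with a probe set, of which 10 were measured and 0 were held by another list. Of the 10, 8 lay above the ceiling in CD74, 6 in Trem2, 2 in Ccrl2 and 2 in CD163. The second list lay at percentile 100, with 9 at least 2-fold above the mean of the others. Genes could enter it through CD74 alone, and it was not run without the background filter, which limits its weight. T or NK cells in a gate set for macrophages are a candidate source. The most abundant genes of the 2 lists in CD74 were Gzma at 13.01 and Ets1 at 12.13, the latter also at 11.25 in Trem2. Cells of the CD74 population that carry these transcripts cannot be told apart from added lymphocytes, since the library is bulk RNA in which all 3 Cd3 genes lay above the ceiling, and a wrong label stays open too.

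In Trem2, neutrophil genes were high, and B cell genes with them. A wider signal range, taken as a rescaling of the values, does not account for the neutrophil genes. They lay at percentile 100 after quantile normalization, with a median 3.89 above that of random lists against 4.34 before. Second lists lay at percentile 100 for neutrophils and for B cells. Genes could enter them through Trem2 alone, and they were not run without the background filter, which limits their weight. For neutrophils, 8 of 11 measured genes were at least 2-fold above the mean of the others, and 7 of the 11 lay above the ceiling in Ccrl2 too. For B cells, 12 of 12 were above, and 11 lay above the ceiling in Ccrl2. Against Ccrl2 alone most of these B cell genes were higher in Trem2, such as Bank1 (13.33 against 11.00). Blnk (9.71 against 10.15) and Cd180 (11.94 against 12.19) were lower. Neutrophils and B cells in the sorted population are thus a candidate source, with Retnlg at 16.81 and Cd79a at 11.80 as abundant markers. Macrophages of the Trem2 population that carry the neutrophil transcripts cannot be told apart from neutrophils, since 11 of the 12 genes lay above the ceiling in a bulk library.

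In CD163, ribosomal protein genes were low, with a median of -2.08 against -0.41 for random lists and 50 of 60 at least 2-fold below the mean of the others. A narrower signal range, taken as a rescaling of the values, does not account for this. After quantile normalization the genes lay at percentile 0, with a median of -1.69 against -0.03 for random lists. Other genes matched on level and genomic span, known for all 60 ribosomal protein genes, were less low. Random lists of them had a 2.5th percentile of -0.71, above the bound of -1.04 chosen beforehand for an effect of short span. By that bound a short genomic span does not account for the low values. Genomic span is not transcript length, and an effect of transcript length was not tested. In CD74 the same genes had a median of 0.62 against -1.53 (percentile 100) and in Ccrl2 -0.12 against 1.07 (percentile 0). A difference between the sorted populations and one in RNA handling both stay open and untested.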
